A study of Canis lupus familiaris with 24 samples.

How the data were processed

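Lymph node aspirates of 4 dogs with B-cell lymphoma at drug-sensitive and drug-resistant phases were profiled on one-colour Agilent arrays, with 3 arrays for each dog and phase, 24 in all. Per the labels' protocols, cells were kept in a stabilising solution, total RNA was column-purified with DNase treatment, and Cy3-labelled RNA was made with a low-input amplification kit. Groups and replicate numbers were taken from the sample titles. The scanner files give spot intensity, deposited by the authors as Agilent Feature Extraction output (version 10.7.3.1, per the file headers and the submitters' processing notes). Per the file headers, the processed signal intensity of a spot was already background-subtracted and detrended within the array, with no normalisation between arrays. The genome build is not given in the sources used here.

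The authors' value table was compared with the scanner files and equalled the raw median intensity of each spot exactly on all 24 arrays (largest difference 0), so it is on a linear scale, uncentred and not normalised between arrays. Neither its scale, its centring nor its direction stayed unknown. Its column medians were 109, 106 and 103 for the sensitive and 112, 103.5 and 100.25 for the resistant arrays of dog 1, 131.75, 130.5 and 141 and then 113, 114 and 115.5 in dog 2, 110, 106 and 102 and then 100, 113 and 109 in dog 3, and 99, 104 and 107 and then 103, 100 and 97 in dog 4.

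Values used here were log2 of the processed signal minus the 75th percentile of each array. Control spots (1417 of 45220) and spots marked as outliers (6 to 195 per array, the highest on sensitive array 1 of dog 3) were left out, 0 spots were saturated, and repeated spots of a probe were averaged. A probe was kept if it lay well above background on all 3 arrays of at least 1 dog and phase, which left 34550 of 43603 probes. The brightest probe stood for each gene, giving 27720 genes or unnamed transcripts. The files give accessions and no gene names. These were matched, without versions, to a RefSeq gene table of the assembly UU_Cfam_GSD_1.0, used for names alone: 832 of 35908 identifiers matched, and 718 of the 832 were measured. None of the 10474 predicted-transcript identifiers matched, and unmatched features were tested without a name.

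Across dogs, limma (version 3.58.1 in R 4.3.3) was fitted to the mean of the 3 arrays of each dog and phase with the dog as a block. The dog pairs the phases, since both come from 1 animal. Within a dog, all 24 arrays in 8 groups shared 1 spread per gene, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold. The dog-by-phase interaction was tested with limma's F-test. Tests were two-sided. On simulated data of 27720 genes, 200 genes each were changed by 1, 2 and 3 on the log2 scale, all in the same data. The test across the 4 dogs recovered 34%, 63% and 86.5% of these changes, with 20 false calls in all. The test within dog 1 recovered 47.5%, 92.5% and 97%, with 10 false calls in all. Each gene's estimated spread was taken as its true spread. Across dogs that estimate had 3 residual degrees of freedom, so the recovery may differ in the real data. The interaction test recovered 93.5% of changes of 3 in dog 1 alone, with 26 false calls. The simulated data for dog 1 and for the interaction held noise between arrays alone, with none between samples of a dog. Their false calls therefore do not describe samples that also vary within a dog.

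The design, the tests, the gene-naming rule and 35 gene lists were fixed before the data were examined, and 8 further lists (such as chemokines, lysosomal genes, pattern and complement receptors and translocon subunits) were written after the gene names but before any value was seen. Lists with at least 3 measured genes (27 of 43, of them 19 fixed before) were tested with camera at a preset correlation of 0.01 against the other genes with a symbol, and again with an estimated correlation. Some genes sit in 2 lists: CCL19, CCL21 and CXCL12 count as stroma markers and as chemokines, CCL5 as an NK marker and as a chemokine, and CXCL10 as an interferon gene and as a chemokine. Named genes were chosen by rule: across dogs, up to 10 of each direction, filled up from genes that moved the same way in all 4 dogs by a mean of at least 2-fold, in order of unadjusted p; in each dog, the 5 largest rises and falls with a symbol whose arrays did not overlap; up to 10 called the same way in all 4 dogs; the 10 of largest range among genes called in opposite directions; and the 4 members of largest change of each list described, with all efflux transporter, drug target and anti-apoptotic genes. A few further list members (COL1A1, PDGFRB, BGN, CCL21, CD4, EIF2AK2 and OAS3) were named after their values were seen. Results for a few genes that this rule picks are not reported here.

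Alternatives were normexp background correction with an offset of 50 and quantile normalisation (on the median in place of the planned mean signal), quantile normalisation or median scaling of the processed signal, the authors' value table scaled to its 75th percentile, other filters, the mean of a gene's probes, slide and replicate blocks, arrays or dogs left out and other fold minimums. The arrays lay on 7 slides and in 2 scan batches (21 and 3 arrays). Slides 1, 3 and 4 held both phases of dogs 1, 2 and 3. Figures were drawn with matplotlib 3.10.9.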

Results

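Gene expression was measured in lymph node cells of 4 pet dogs with B-cell lymphoma, a cancer of B lymphocytes that is treated with chemotherapy. The dogs were a Shih Tzu (dog 1), a Doberman (dog 2) and 2 French Bulldogs (dogs 3 and 4). Each dog was sampled by fine-needle aspiration while its lymphoma responded to drugs (sensitive phase) and again when it no longer did (resistant phase). Each of the 8 groups, a dog in 1 phase, had 3 one-colour arrays, 24 in all, and nothing states whether the 3 came from 1 aspirate or from several. The number of arrays limits the precision. Between 71.0% and 80.9% of the spots of an array lay well above background, and its 75th percentile of signal lay between 676 and 1117. After filtering, 27720 genes or unnamed transcripts were tested, of which 718 (2.59%) carried a gene symbol. The named genes below therefore come from a small part of the array. Arrays of 1 group correlated with a median r of 0.992 across transcripts, arrays of 1 dog in different phases with 0.976 and arrays of different dogs with 0.952. For each of the 8 groups, the most similar of the others was that of the same dog in the other phase. Changes are given as resistant minus sensitive on the log2 scale, relative to each array's 75th percentile, with standard errors (SE) from 4 dogs. Within a dog, the SE rests on 3 arrays per phase and on 1 spread per gene shared by all 8 groups. It does not give the spread of that dog's own arrays.

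The study asked which genes change between the phases. Across the 4 dogs, no single gene passed, but the genes with the most even changes were mostly lower in the resistant phase. CXCL12, a chemokine made by stromal cells, had a mean change of -2.03 (SE 0.22, n = 4 dogs, lower in 4 of 4), and F3, which codes for tissue factor, the starter of blood clotting, of -2.36 (SE 0.28). The leukocyte surface antigen gene CD52 had a mean change of -1.87 (SE 0.38), the steroid dehydrogenase gene HSD17B14 of -1.83 (SE 0.38) and INPP5A, an inositol phosphate phosphatase gene, of -1.45 (SE 0.31). The transcription repressor gene GFI1 had a mean change of -1.16 (SE 0.14), with single dogs between -1.36 and -0.90. GNB3, a G protein subunit gene, was the 1 named gene that was higher in all 4 dogs by a mean of at least 2-fold, at 1.10 (SE 0.23), and its other probe gave changes of 0.33, 1.66, 0.64 and 0.14 in dogs 1 to 4. TACR1 (-1.24, SE 0.23) and IL1RN (-1.12, SE 0.23) were also lower in each dog. ZFPM2 was at least 2.56-fold lower in dog 2 and 2.29-fold lower in dog 3, and TJP1 was at least 3.31-fold lower in dog 1, where "at least" marks a gene not well above background on any array of 1 phase. The bright phase's mean is then set against the dim arrays' lowest signal of a probe well above background, or the gene's own signal where that is higher. The other TJP1 probe had changes of 0.87 in dog 1 and 0.52 in dog 4. F3 was well above background on 1 of 3 resistant arrays in dogs 1 and 4.

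None of these genes passed limma's test over the 8 group means with the dog as a block, in which 0 of 27720 reached an adjusted p under 0.05 and the lowest was 0.369. At an unadjusted p under 0.05 there were 1603, 292 higher and 1311 lower, where chance gives 1386. All 4 dogs moved the same way for 15.1% of the transcripts, against 12.5% by chance, with 2232 higher and 1964 lower. Among those with a mean change of at least 2-fold, 831 were lower in all 4 dogs (46 with a symbol) and 23 were higher (1 with a symbol). Counting the 24 arrays instead of the 8 means gave 1741 genes with the group as a random block and 2503 with the slide as a further block, both resting on 1 correlation shared by all genes.

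Of the gene lists, markers of fibroblasts and stroma lay lower across the dogs, with 9 measured members. COL1A1, coding for a collagen, had a mean change of -1.20 (SE 0.26), COL1A2 of -1.66 (SE 0.43) and CXCL12 of -2.03. DCN, coding for the matrix protein decorin, fell in dogs 1 and 3 (-2.49 and -3.75), was at least 1.88-fold lower in dog 2 and had a change of 0.12 in dog 4. No member passed over all genes, and 3 passed adjusted over the list alone; 3 of the 9 were lower in every dog. BGN and PDGFRB had mean changes of -0.15 and 0.00. The list's camera test gave an adjusted p of 0.00758 with the preset correlation. Over 12 alternatives it ran from 3.78e-05 to an adjusted p = 0.960 with an estimated correlation. Of the other 5 COL1A2 probes, 2 had changes of -0.14 and -0.13 in dog 1, against -3.13 for the probe used. The mean change of the 9 members was -0.72 in dog 1, -1.28 in dog 2, -1.49 in dog 3 and -0.54 in dog 4 (SE 0.07 each). In dog 1, 3 members fell and 1 rose, and the list's camera test there gave an adjusted p of 0.481. With the slide as a block the list's mean changes in dogs 1 to 3 were -0.62, -1.37 and -1.66. That fit takes the change within the 1 slide that held both phases, where 3 arrays of 1 phase stood against 1 of the other. In dog 4 no slide held both phases. The slide as a random block, which cannot remove a slide difference there, gave -0.50.

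Chemokines, which attract immune cells, were lower as a list of 18 measured members (mean change -1.04; adjusted p = 0.0355, but adjusted p = 0.960 with an estimated correlation). In dogs 1 to 4, 10, 8, 7 and 2 members fell and 2, 0, 0 and 4 rose, and the mean change in dog 4 was 0.12. CCL4 had a mean change of -2.90 (SE 1.11), CCL3 of -2.63 (SE 1.17) and CCL5 of -2.43 (SE 1.10), and 1 member, CXCL12, passed adjusted over the list alone. Subunits of the translocon and signal peptide machinery, which moves new proteins into the endoplasmic reticulum, were higher as a list of 15 (mean change 0.14; adjusted p = 0.0355, but adjusted p = 0.960 with an estimated correlation), with 6 members higher in all 4 dogs and 0 past the list alone. SPCS2 had a mean change of 0.40 (SE 0.15). Over 12 alternatives the lowest adjusted p was 0.000368 for the chemokine list and 0.00457 for the translocon list. Without dog 1 the adjusted p was 0.202 for chemokines and 0.359 for the translocon list, without dog 2 it was 0.108 and 0.113, and without dog 3 it was 0.0576 for chemokines. The T cell list (mean change -1.54; adjusted p = 0.0995) and the list of NK and cytotoxic cells (-2.16; adjusted p = 0.142) did not pass, nor did that of follicular and other dendritic cells (-0.53; adjusted p = 0.159). In the last of these, 4 of 5 members passed adjusted over the list alone, among them the growth factor receptor gene FLT3 (-1.09, -0.73, -1.37 and -0.79 in dogs 1 to 4) and CLU (-0.93, SE 0.29), with CD1C higher at 0.63 (SE 0.18). The other tested lists had adjusted p from 0.0591 to 0.948.

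**Figure D1:**
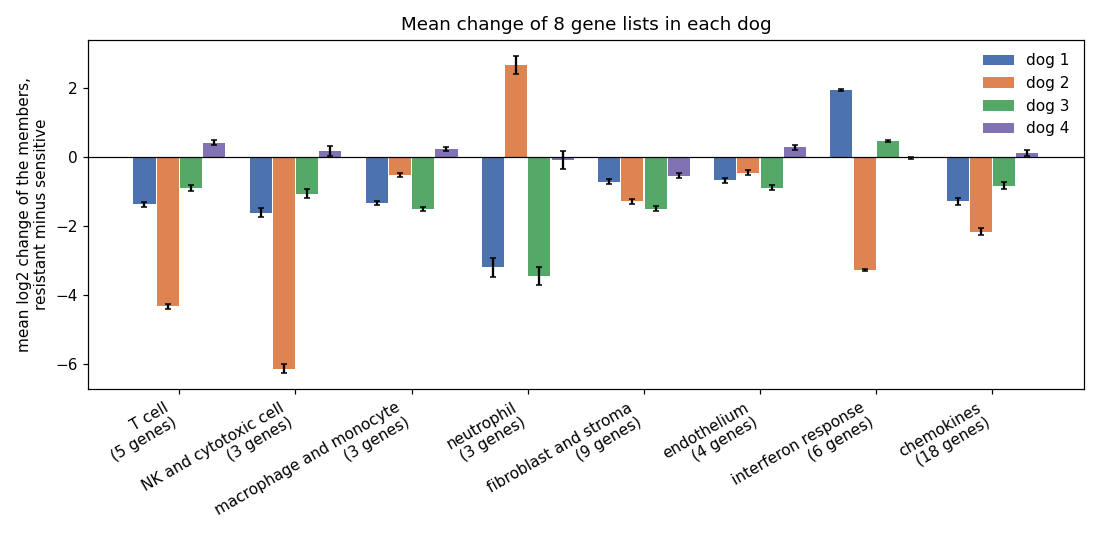
Mean log2 change (resistant minus sensitive, vertical axis) of the members of 8 gene lists in dogs 1 to 4 (bars), with standard errors. The standard error rests on 3 arrays per phase and on 1 spread per list shared by all dogs. Stroma markers were lower on average in all 4 dogs (-0.72, -1.28, -1.49 and -0.54), though their list did not pass camera's test in dog 1 (adjusted p = 0.481). Neutrophil genes and interferon-response genes moved in opposite directions in different dogs, though the neutrophil list passed camera's test in no dog (adjusted p from 0.0776 to 0.908).

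In dog 1, interferon-response genes rose and neutrophil genes fell. MX1, coding for an interferon-induced antiviral GTPase, rose by 3.14 (SE 0.03), and the interferon-induced chemokine gene CXCL10 by 2.88 (SE 0.08). CCL19, an attractant of T cells and dendritic cells, rose by 2.50 (SE 0.04), and MAL, a membrane protein gene of T cells, by 3.35 (SE 0.15), being well above background on 1 of 3 sensitive arrays. GRIN2B, a glutamate receptor subunit gene, was at least 2.25-fold higher, a call that ended after normexp background correction with quantile normalisation (below, normexp). SERPINA1, coding for alpha-1 antitrypsin, fell (-5.69, SE 0.06), with its other probe at -3.69. LOC448801 (-5.51, SE 0.10), the neutrophil cathelicidin gene CAMP (-5.46, SE 0.47) and the complement receptor gene C5AR1 (-4.93, SE 0.12; 2 of 3 resistant arrays well above background) fell as well. ADGRE2, a myeloid adhesion receptor gene, was at least 15.2-fold lower.

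Of the interferon-response list, 5 of 6 measured members rose in dog 1 (5 adjusted over the list alone), with OAS2 at 1.92 (SE 0.06), OAS1 at 1.65 (SE 0.04) and EIF2AK2 at 1.44 (SE 0.08), while OAS3 stayed under 2-fold at 0.69. The list's adjusted p was 1.84e-05, and over 3 alternatives it ran from 6.6e-07 to an adjusted p = 0.00901 with an estimated correlation. Its mean change of 1.96 was 1.93 within slide 1, where there was 1 resistant array. All 3 measured neutrophil members fell (3 adjusted over the list alone), with MMP9 at -1.97 and CXCR2 at -2.17, though the list test gave an adjusted p of 0.19 and the CXCR2 call ended within slide 1 (-0.60). The mean neutrophil change of -3.20 was -2.42 within slide 1. T cell markers fell for 3 of 5 members (3 adjusted over the list alone; list adjusted p = 0.244), namely CTLA4, at least 9.73-fold, CD28 (-1.19; 1 of 3 resistant arrays well above background; -0.57 and no call without resistant array 1) and ICOS, below background in both phases. The CD28 and ICOS calls ended after quantile normalisation. The translocon list was higher, with a mean change of 0.25 and 0 of 15 members past 2-fold. Its adjusted p was 0.00069, and from 0.000157 to an adjusted p = 0.0513 with an estimated correlation over 3 alternatives.

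In limma's fit to the 24 arrays, 3310 transcripts passed an adjusted p under 0.05 and 2-fold in dog 1, 1061 up and 2249 down (35 and 123 with a symbol). P-values within a dog measure the spread between the 3 arrays of a group, which may be technical. Of the calls, 32.1% were up, against 46.6% with each array scaled to its median, 46.5% after quantile normalisation and 37.5% after normexp and quantile normalisation. There were 847 calls after normexp, 1294 in the authors' value table and 1538 among probes well above background on all 24 arrays. With the slide as a block there were 2443. Within slide 1, where 3 sensitive arrays were set against 1 resistant array with the spread of all groups, the changes were the same as with that block, and 2382 were called, where 1966 of the 3310 were called in the same direction and 184 changed sign. Median scaling moved the median change of all transcripts from -0.06 to 0.12 in dog 1 and from 0.11 to 0.26 in dog 2.

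In dog 2, T cell, NK cell and interferon-response genes fell and the neutrophil genes CAMP and MMP9 rose. CXCL10 (-8.40, SE 0.08) and KLRD1, an NK cell receptor gene (-6.42, SE 0.08), fell, each with 2 of 3 resistant arrays well above background, as did the chemokine genes CCL4 (-6.85, SE 0.08) and CCL3 (-6.43, SE 0.33). IL21, a cytokine gene of helper T cells, was at least 85.6-fold lower. CCR3, an eosinophil chemokine receptor gene, rose by 5.21 (SE 0.21), CAMP by 4.49 (SE 0.47) and PDE6B, a phosphodiesterase gene, by 2.63 (SE 0.08). Of 3 neutrophil genes 2 rose, and their list did not pass camera's test in dog 2 (adjusted p = 0.0776). The chloride channel gene CFTR rose by 3.02 (SE 0.79), with 1 of 3 sensitive arrays well above background, and that call ended with the slide as a block and after normexp.

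All 5 measured T cell markers fell in dog 2 (5 adjusted over the list alone), with CD28 at least 29.6-fold lower, ICOS not well above background on any resistant array, CD8A at -4.84 (SE 0.37) and CD4 at -1.39 (SE 0.15). The T cell list and the NK list, where 3 of 3 fell (3 adjusted over the list alone), each had an adjusted p of 0.0146. Over 3 alternatives these ran from 0.000201 (T cells) and 0.000252 (NK cells) to an adjusted p = 0.0650 with an estimated correlation. Of the interferon list 5 of 6 fell (5 adjusted over the list alone), with MX1 at -4.33 (SE 0.03) and OAS2 at -2.80 (SE 0.06), at an adjusted p of 0.000768 (5.9e-07 to an adjusted p = 0.0409 with an estimated correlation). Stroma markers fell for 6 of 9 members (6 adjusted over the list alone), such as CCL19 at -2.88 and CCL21 at -2.80 (adjusted p = 0.0146). That list, which held these chemokines beside its collagens, ran from 5.8e-05 to an adjusted p = 0.0650 with an estimated correlation, and its DCN call, at 0 of 3 resistant arrays well above background, ended after normexp and with the mean of probes (other probe 0.03). Lysosomal genes fell for 6 of 22 members and rose for 1 (6 and 1 adjusted over the list alone), with NPC2 at -2.38 and CTSD at -2.25 (list adjusted p = 0.0145; 3.48e-06 to an adjusted p = 0.0739 with an estimated correlation). MHC class II genes fell for 2 of 7 (2 adjusted over the list alone), CTSS (-1.34) and DLA-DQA1 (-1.06), the second call ending with median scaling (list adjusted p = 0.0237; 0.000252 to an adjusted p = 0.0650 with an estimated correlation).

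Chemokines fell for 8 of 18 members in dog 2 and for 9 adjusted over the list alone (adjusted p = 0.0371; 0.000201 to an adjusted p = 0.0650 with an estimated correlation). The pattern and complement receptor list fell for 4 of 9 (4 adjusted over the list alone), such as the inflammatory caspase genes CASP4 at -3.22 and CASP12 at -2.97 (adjusted p = 0.0342; 0.000349 to an adjusted p = 0.110 with an estimated correlation). The DNA repair list was higher (adjusted p = 0.0295; 0.0402 to an adjusted p = 0.0650 with an estimated correlation). That list no longer passed under 2 of 3 alternatives. Of its 5 members 1 rose and 1 fell, with the same counts adjusted over the list alone. The member that fell was MGMT, which removes alkyl groups from DNA. It fell by 1.60, a call that ended after normexp. The translocon list was higher with a mean change of 0.19 and 0 of 15 members past 2-fold (adjusted p = 0.0146; 0.0195 to an adjusted p = 0.0727 with an estimated correlation). In limma's fit 3832 transcripts were called in dog 2, 1104 up and 2728 down (30 and 140 with a symbol). The share up was 28.8%, against 40.6% with median scaling, 36.3% after quantile normalisation and 19.4% after normexp and quantile normalisation. Leaving out sensitive array 1 gave 736 calls up and 2670 down, and leaving out sensitive array 3 gave 1393 and 2706. There were 1550 calls after normexp, 2158 in the authors' value table and 2152 among probes well above background on all 24 arrays. With the slide as a block there were 3295, and within slide 3 (1 sensitive and 3 resistant arrays) there were 3090, with 2843 of the 3832 called in the same direction. The mean changes of the T cell list (-4.33) and of the interferon list (-3.29) were -4.32 and -3.26 within that slide.

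In dog 3, stroma genes and the neutrophil genes CAMP and MMP9 fell. CFTR (-5.47, SE 0.79), CAMP (-5.42, SE 0.47) and MMP9, coding for a matrix protease of neutrophils (-4.92, SE 0.11; 2 of 3 resistant arrays well above background), fell, as did the secreted protease inhibitor gene SLPI (-4.69, SE 0.56) and the chemokine gene CCL20 (-4.68, SE 0.06). Of the other MMP9 probes, 1 gave -4.60 and 1 gave -1.59 in dog 3. The other SLPI probe gave -9.40, and the SLPI probe used gave -6.30 within slide 4 (1 resistant array). PON2, a paraoxonase gene, rose by 1.74 (SE 0.10), LOC448801 by 1.35 (SE 0.10) and the myosin gene MYH7 by 1.29 (SE 0.17), and these calls ended after normexp. The other MYH7 probes had changes from 0.15 to 1.29 in dog 3. GRIN2B was at least 3.52-fold and the cytokine gene IL6 at least 2.97-fold higher, with the same loss after normexp. Stroma markers fell for 6 of 9 members (6 adjusted over the list alone), with DCN at -3.75 (SE 0.07), COL1A1 at -1.45 (SE 0.05) and COL1A2 at -1.40 (SE 0.04; call ended with the mean of probes). The list's adjusted p was 0.000256 (1.02e-06 to an adjusted p = 0.0176 with an estimated correlation). The interferon list was higher with a mean change of 0.47 and 0 of 6 members past 2-fold (adjusted p = 0.00738; 0.00266 to an adjusted p = 0.0842 with an estimated correlation).

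Of the other cell markers in dog 3, 3 of 5 T cell genes fell (list adjusted p = 0.347), as did 2 of 3 macrophage genes (FCGR1A at -2.65, CD163 at -1.33; list adjusted p = 0.0620) and 2 of 3 neutrophil genes (list adjusted p = 0.156), with the same counts adjusted over the lists alone. In limma's fit 1877 transcripts were called, 371 up and 1506 down (13 and 91 with a symbol). The share up was 19.8%, against 27.2% with median scaling, 11.5% after normexp and quantile normalisation and 9.30% in the authors' value table. Leaving out resistant array 1 gave 791 calls up and 1585 down, and leaving out resistant array 2 gave 270 and 1455. There were 593 calls after normexp, 871 in the authors' value table and 874 among probes well above background on all 24 arrays. With the slide as a block there were 1880, and within slide 4 (3 sensitive arrays and 1 resistant array) there were 1793, with 1405 of the 1877 called in the same direction.

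In dog 4, the drug efflux gene ABCB1 rose, and no T cell, NK cell, macrophage or neutrophil marker was called. Among probes other than those used, 1 of MMP9 had a change of 2.71, 1 of CTLA4 of 1.34 and 1 of CD8A of -1.03. ABCB1, coding for the drug efflux pump P-glycoprotein, rose by 3.67 (SE 0.08), from -3.03 ± 0.05 to 0.64 ± 0.03 (SD, n = 3 arrays), and its other probe by 3.55. The chloride channel gene CLCN1 rose by 2.88 (SE 0.38; 2 of 3 sensitive arrays well above background), PDE1A was at least 2.63-fold and IL3 at least 1.65-fold higher, and these 3 calls ended after normexp. RHPN2 fell by 1.87 (SE 0.05), with its other 2 probes at -2.04 and -1.85, and CXCL12 fell by 1.69 (SE 0.05). GUCY2D, coding for a retinal guanylate cyclase, was at least 2.77-fold lower. DEFB122, a defensin gene, was at least 5.00-fold lower and IL13RA2 (2 of 3 sensitive arrays well above background) at least 1.63-fold. All 3 calls ended after normexp, and the other DEFB122 probe (1.76) and the other IL13RA2 probes (0.09 and 1.21) did not fall.

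Of 9 stroma markers 2 fell in dog 4 (2 adjusted over the list alone), CXCL12 and CCL19 (-1.28, SE 0.04), at an adjusted p of 0.00193 (0.00296 to an adjusted p = 0.0408 with an estimated correlation). The MHC class II list was lower with a mean change of -0.23 and 0 of 7 members past 2-fold (adjusted p = 0.00781; 0.0110 to an adjusted p = 0.0408 with an estimated correlation). In limma's fit 1542 transcripts were called, 1125 up and 417 down (37 and 17 with a symbol). The share up was 73.0%, against 66.3% with median scaling, 50.9% after quantile normalisation, 52.8% in the authors' value table and 44.4% after normexp and quantile normalisation. There were 180 calls after normexp, 235 in that table, 439 among probes well above background on all 24 arrays and 2583 without a filter. The 3 resistant arrays were alone on 1 slide and in 1 scan batch, so batch and phase cannot be told apart in dog 4, and the slide as a random block gave 1111.

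The dogs were then compared with each other. Several interferon and neutrophil genes rose in 1 dog and fell in another. CXCL10 rose by 2.88 in dog 1 and fell by 8.40 in dog 2, with 0.07 and -0.16 in dogs 3 and 4, and MX1 went from 3.14 in dog 1 to -4.33 in dog 2. CAMP fell in dogs 1 and 3 and rose in dog 2 (-5.46, -5.42 and 4.49), as did MMP9 (-1.97, -4.92 and 2.52), of which 1 other probe gave -0.86, -1.59 and -0.03 in these dogs and 2.71 in dog 4, against -0.22 for the probe used. ABCB1 fell in dogs 2 and 3 (-2.91 and -1.46) and rose by 3.67 in dog 4. Its other probe gave -3.48, 1.03 and 3.55 in these dogs, so the fall in dog 3 rests on 1 probe. CFTR rose in dog 2 and fell in dog 3. MAL rose by 3.35 in dog 1, was at least 5.04-fold lower in dog 2 and fell in dogs 3 and 4 (-2.96 and -1.06). LOC448801 fell in dogs 1, 2 and 4 and rose in dog 3. The interaction of dog and phase passed limma's F-test for each of these 8 genes, with adjusted p between 1.56e-23 (MX1) and 1.62e-05 (CFTR). It passed for 21848 transcripts (78.8%), of which 1049 were called up in 1 dog and down in another. This test compares the changes with the spread between the 3 arrays of a group alone. The 1049 became 650 with the slide as a random block, 607 without array 2 and 614 without array 3 of every group, 435 among probes well above background on all 24 arrays, 356 in the authors' value table and 216 after normexp.

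**Figure D2:**
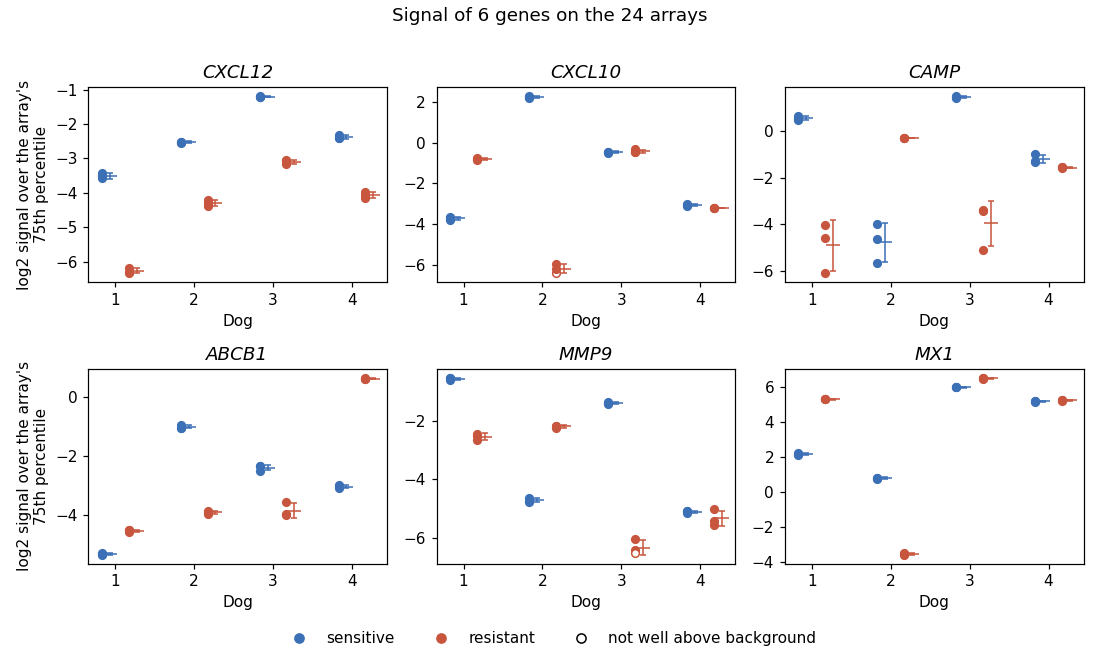
Log2 signal relative to the array's 75th percentile (vertical axis) of CXCL12, CXCL10, CAMP, ABCB1, MMP9 and MX1 on the 3 arrays per phase of each dog (points), with means and SD. CXCL12 was lower in the resistant phase of all 4 dogs (-2.77, -1.77, -1.89 and -1.69), while ABCB1 was 3.67 higher in dog 4 and 2.91 lower in dog 2; open points were not well above background.

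Shared changes of at least 2-fold ran mostly downward. With no fold minimum, 2840 transcripts were called up and 2580 down in 3 or 4 dogs. At 2-fold, CXCL12 (-2.77, -1.77, -1.89 and -1.69 in dogs 1 to 4), HSD17B14 (-1.02, -2.52, -2.76 and -1.02) and F3 (-2.76, -3.09, -1.93 and -1.65) were called down in all 4 dogs. No named gene was called up in all 4. The CXCL12 calls in dogs 1 and 2 ended after normexp. With the slide as a block the CXCL12 changes in dogs 1 to 3 were -2.79, -1.75 and -1.84. In dog 4, where no slide held both phases, the slide as a random block gave -1.70. The F3 change in dog 1 was -4.48 within slide 1 (1 resistant array), its resistant level being -6.85 ± 2.21 (SD, n = 3 arrays). The other HSD17B14 probe gave -0.64 in dog 1 and -0.93 in dog 4. In 3 or 4 dogs, 19 transcripts were called up and 486 down, where independent lists of these sizes share 3.39 and 18.9. These were 4 and 77 after normexp, 5 and 134 in the authors' value table, and 9 and 231 among probes well above background on all 24 arrays. Opposite calls also exceeded the number independent lists share in 5 of the 6 pairs of dogs, with 625 against 194 in dogs 1 and 2 and 189 against 87.7 in dogs 1 and 3, so that number is not the value without a shared change. With the phases of whole dogs swapped, 99 to 458 transcripts were called the same way in 3 or 4 dogs, against 505, the highest with dog 4 swapped. In all 4 dogs it was 2 up and 43 down, against 0.023 and 0.181. Of genes with a symbol, 42 were down in at least 3 dogs and 0 up. In dogs 1 to 3, whose arrays were scanned in 1 batch, 377 were down and 3 up. Across transcripts, which are not independent replicates, the changes of dogs 2 and 3 correlated most (Pearson r = 0.324, Spearman rho = 0.205). The other 5 of the 6 pairs lay between -0.01 and 0.12 (Pearson).

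Of the measured drug efflux and apoptosis genes, 0 were called in all 4 dogs. Of the drug efflux transporters, 4 were measured. ABCC5 fell by 2.23 (SE 0.05) and ABCC1 rose by 1.06 (SE 0.03) in dog 2, the ABCC1 call ending after quantile normalisation, and ABCC2 was not called in any dog, with changes from -0.42 to 1.06. The ABCB1 change in dog 1 was 0.79, under 2-fold, and its other probe gave -1.27 there and 1.03 in dog 3, against -1.46 for the probe used. The call in dog 3 also ended with the mean of both probes. The list's adjusted p was 0.947 across the dogs. Of 7 anti-apoptotic genes, BCL2L2 fell in dog 1 (-1.58, SE 0.50; 1 of 3 resistant arrays well above background) and BCL2L1 in dog 2 (-1.27, SE 0.51), calls that ended after normexp and without 1 array (-1.03 without resistant array 2 of dog 1 and -0.66 without sensitive array 3 of dog 2), and BCL2L2 was at -0.07 with the slide as a block. BCL2L2 had a change of 1.24 (SE 0.50) in dog 4, which passed adjusted over the list alone but not over all genes (adjusted p = 0.0534). MCL1 changed by less than 2-fold in each dog (0.03 to 0.43). BCL2 had changes of -0.83, -0.29, 0.36 and 0.14, and the 6 pro-apoptotic genes gave no call in any dog (list adjusted p = 0.947 across the dogs). The B cell marker MS4A1, coding for CD20, had changes of -0.29, 0.16, 0.21 and -0.28, and CD40 of 0.35, 0.07, 0.21 and 0.04, with no call. The lists of drug targets and of cell cycle genes had 0 measured members with a symbol.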

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

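The tests in this part were chosen after the results were seen, except the counts of other splits, which were set before those counts were known. The splits that keep groups whole were added afterwards.

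The interaction of dog and phase passed for 21848 transcripts, and 1049 were called up in 1 dog and down in another. This test measures the spread between the 3 arrays of a dog and phase, which may be repeats of 1 sample, so it does not show that dogs differed by more than separate samples of 1 dog would. The range between the lowest and highest change of a dog was 11.3 for CXCL10, 9.95 for CAMP, 8.49 for CFTR, 7.47 for MX1, 7.44 for MMP9, 6.86 for LOC448801, 6.58 for ABCB1 and 6.31 for MAL. The mean change ranged over 6.13 between dogs for the neutrophil list, 5.24 for the interferon list and 2.39 for the list of red cell and platelet genes (1.08 in dog 2 and -1.32 in dog 1).

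In a test for 1 value standing apart among 4, dog 4 lay away from the other dogs for CD52 (0.947 of the range) and TJP1 (0.853), with changes of -0.44 and -0.45, though TJP1 was not well above background on any resistant array of dog 1. Dog 2 lay away for the mean of the lysosomal list (0.938), at -0.68 against -0.03 to 0.02. Of 39 such sets of 4 dogs, 3 stood out, and chance gives about 1 in 20.

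Other splits of the arrays were counted for each result. Swapping phases within dogs gives 8 splits, too few for a share under 0.05. The 0 genes across the dogs were matched by all 8 (highest other 0), as any count would match 0. The 1603 genes at an unadjusted p under 0.05 were matched by 2 of 8 (highest other 2125). The 3 lists across the dogs were matched by 3 of 8 (highest other 4). The 6 arrays of a dog give 10 splits, also too few, and 1 of 10, the real split, gave as many calls in each dog, with 3310 against a highest other of 79 in dog 1, 3832 against 2 in dog 2, 1877 against 231 in dog 3 and 1542 against 2 in dog 4. In dogs 1 and 3 that other split followed the slides, and with the slide as a block the real one gave 2443 and 1880. Of 100 splits within the dogs, 1 gave as many transcripts with an interaction (21848, highest other 21701) and 1 as many called the same way in 3 or 4 dogs (505, highest other 110). For the 16 list calls in single dogs it was 2 of 100 (highest other 16). In each of these counts the highest other was the split that kept the real groups of arrays and swapped the phases of 1 dog. Nearly all of the 100 splits broke up the 3 arrays of a dog and phase. If those arrays are repeats of 1 sample, such splits set samples against array noise and decide nothing about chance. The splits that keep these groups of 3 whole number 8, too few for a share under 0.05. Among them 4 gave as many interactions (highest other 22173) and 1 as many shared calls (505, highest other 458). All 8 gave the same 16 list calls. Swapping a dog's phases only turns the sign of its changes, and the list tests are two-sided, so that count was fixed in advance. The 458 came from swapping the phases of dog 4, whose resistant arrays formed the second scan batch, and dogs 1 to 3, scanned in 1 batch, shared 377 down and 3 up.

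Markers of cells other than the lymphoma were lower on average in dogs 1 to 3, with mean changes of -1.11, -2.65 and -1.28 over 20 genes of T cells, NK cells, macrophages and stroma, of which 9, 15 and 12 fell and 1, 1 and 0 rose, and none of the 4 lists passed in dog 1 (adjusted p from 0.19 to 0.591). A difference between slides as the whole cause is argued against, because with the slide as a block the means were -1.05, -2.68 and -1.42 (SE 0.05 each; 95.1%, 101% and 111% kept) while 184, 30 and 56 of all calls in these dogs changed sign, although 1 phase of each dog had a single array on the shared slide, taken to vary like arrays of other groups. An evenly lower share of all other cells is argued against in dog 2, where list means ran from -6.14 (NK cells) to 2.69 (neutrophils), further apart than shuffled members (permutation p = 1.0e-05, the smallest these draws can give). In dogs 1 and 3 it stays open (permutation p = 0.383 and 0.183), and the lists there were all lower, from -3.20 to -0.67 and from -3.45 to -0.88. The dog 2 test covers an even change alone, and an uneven change in the makeup of its aspirates was not tested. The stroma, T cell and neutrophil changes of dogs 1 to 3 may reflect the makeup of the aspirates, the treatment or the lymphoma cells themselves. The design does not separate these.

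The rise of ABCB1 in dog 4 could come from the resistant phase or from the slide and scan batch that hold its 3 arrays and no others. A faulty ABCB1 probe is argued against in dog 4. The other ABCB1 probe, well above background on 2 of 3 sensitive and 3 of 3 resistant arrays there, rose by 3.55 (SE 0.76, limma adjusted p = 0.000928 over 34307 probes). The 2 probes differed in sign in dog 1 (0.79 for the probe used and -1.27) and in dog 3 (-1.46 and 1.03). Between slides within 1 dog and phase ABCB1 shifted by at most 0.19, but the second scan batch holds that phase of dog 4 alone. Batch and phase cannot be told apart there.

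Of 6 interferon genes 5 rose in dog 1 and 5 fell in dog 2. If they followed the T and NK cells, they would fall with them in both dogs. Yet in dog 1 the interferon mean was 1.96 (SE 0.03) while the T and NK means were -1.37 and -1.61. Neither of these 2 lists passed camera's test there (adjusted p = 0.244 and 0.19), and 3 of 5 and 2 of 3 members fell. The rise of the interferon mean still argues against this explanation in dog 1, within the spread between arrays alone. In dog 2, where the T and NK means were -4.33 and -6.14, it remains open. A slide difference as the whole cause is argued against too, since with the slide as a block the means were 1.93 and -3.26 (SE 0.04 each; at least 98.9% kept), again with a single array of 1 phase on the shared slide. An infection, or a drug given near sampling in 1 of the phases, could also be behind it, and neither was tested.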

How the results depend on the processing

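Within-slide fits and the list test against all features were chosen after seeing the data. The across-dog count stayed at 0 under each scaling, filter and left-out array or dog tried. It was 2503 with the slide as a block and 1741 with the dog and phase as a random block. Each of these fits takes 1 correlation for all genes, which was 0.804 in the fit without the slide. Both used the 24 arrays in place of the 8 means. With 24 arrays as separate samples, which takes the 3 arrays of a dog and phase as independent, it was 7822, and 3858 with the replicate number added as a block. The replicate numbers do not pair the arrays (correlations of deviations from -0.13 to 0.09, 0 of 12 over 0.1). Within dogs the number as a block gave 3172, 3722, 1805 and 1437 calls and ended 2 of the 16 list calls, chemokines and pattern receptors in dog 2.

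After normexp and quantile normalisation the calls in dogs 1 to 4 were 847, 1550, 593 and 180, with 81 shared by 3 or 4 dogs and 216 opposite. In the authors' value table they were 1294, 2158, 871 and 235, with 139 and 356. Keeping probes well above background on all 24 arrays gave 1538, 2152, 874 and 439, with 240 and 435, and fewer transcripts were tested there. No filter gave 2583 in dog 4. With no fold minimum the counts were 15256, 16556, 12355 and 12856 (5420 shared, 2840 up and 2580 down), and at 1.5-fold 5905, 6809, 3538 and 3659. The slide as a random block gave 650 opposite calls. Leaving out arrays gave 2280 to 3892 calls in dog 1, 3334 to 4099 in dog 2, 1617 to 2478 in dog 3, 1035 to 2010 in dog 4, 454 to 495 shared and 16865 to 21500 with an interaction, and 607 to 1434 opposite calls (607 without replicate 2 and 614 without replicate 3 of every dog and phase). The cause was not tested where none is given.

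Lists called across the dogs numbered 3, but 0 with an estimated correlation, 0 with fry, 1 after quantile normalisation, 7 with all features as background and 1 to 4 when a dog was left out, with 1 without dog 1. In single dogs, 16 list calls became 5 with an estimated correlation. Over 12 alternatives the stroma list's adjusted p across dogs ran from 3.78e-05 to 0.960. The 0.960 came with an estimated correlation of 0.0125, near the preset 0.01, and with 3 residual degrees of freedom.

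Of 134 calls of named genes in a dog, 79 passed under each alternative that gave them a value. The filter on all 24 arrays kept 70 of the 134, of which 53 passed throughout. Of 3004 values, 205 no longer passed and 2 reversed. Both were for DIO2, dog 1, not above background in either phase, at 0.00903 both with the slide as a block and within slide 1, which give 1 estimate. Signal over background limits the dim probes most: in dogs 1 to 4, 812, 755, 477 and 615 calls had 1 phase without any array well above background.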

Other observations

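The counts and lists in this part come from the planned tests, and these genes were singled out after their values were seen. Cytokines other than chemokines were lower as a list of 20 measured genes across the dogs, with a mean change of -0.57 and 7 members lower and 2 higher in all 4 dogs, but the list did not pass (adjusted p = 0.0591 with the preset correlation, adjusted p = 0.960 with an estimated correlation). IL1A, an alarm cytokine gene, was at least 5.51-fold lower in dog 1 and fell by 2.42 (SE 0.52) in dog 2, where 1 of 3 resistant arrays lay well above background, and both calls ended after normexp. IL33 fell by 2.17 (SE 0.08) in dog 2 and by 1.41 (SE 0.08) in dog 3. CD38, a surface enzyme gene of plasma cells and activated lymphocytes, fell by 4.22 (SE 0.04) in dog 2 and had changes of -0.95, -0.91 and -0.31 in the other dogs. HSPB1, coding for a small heat shock protein, fell by 2.81 (SE 0.05) in dog 2 and had a change of 0.99 in dog 1. SELENOP, a selenium carrier gene, fell by 2.91 (SE 0.05) in dog 2 and by 1.58 (SE 0.05) in dog 3, and its other 2 probes lay at -2.81 and -2.96 in dog 2.

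Macrophage markers split in dog 2. The Fc receptor gene FCGR1A rose by 1.62 (SE 0.10) and FCER1G fell by 2.41 (SE 0.14), while in dog 1 FCGR1A fell by 3.67 (SE 0.10). The endothelial receptor gene KDR fell by 2.08 (SE 0.24) in dog 2 and by 2.92 (SE 0.24) in dog 3 and was at least 2.54-fold lower in dog 1, the dog 1 call ending after normexp. VWF, another endothelial gene, gave no call in any dog, with changes from -0.41 to 0.17.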
